A study of Mus musculus with 6 samples.

How the data were processed

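Pituitary glands were collected from male C57BL/6J mice aged 8 to 12 weeks, kept in 12 hours of light and 12 of darkness, at zeitgeber time 12. Per the labels, 3 pools of 3 glands were made for wild-type and for Bmal1-/- mice, and biotin-labelled cRNA was prepared from 1 ug of total RNA of each pool for an Affymetrix mouse array. Each pool is 1 replicate, and the labels number them 1 to 3 in wild type and 4 to 6 in Bmal1-/- mice. The labels give no batch, slide or scan information.

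The deposited table holds 1 intensity per probe set and array on a linear scale. Per the submitters' processing notes, these values come from MAS5, the Affymetrix algorithm that summarises the probe pairs of a probe set and scales each array. The MAS5 version, the target value and the detection calls are not given in the sources used here. In the files, the mean intensity after trimming 2% of probe sets from each end was 100.0 on all 6 arrays, as scaling of every array to 1 target would leave it. MAS5 subtracts a mismatch-based background, so low values are noisy, and no detection calls were used here.

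Of the 22690 probe sets, 64 are array controls and were left out of the tests. The platform annotation pairs 20393 probe sets with 1 gene, 691 with several and 1606 with none listed. No gene is named here from a probe set with several. Gene IDs matched the mouse RefSeq gene table for 99.9% of the single-gene probe sets, and no symbol needed updating. Chromosome positions in that table were used only to find which genes neighbour Arntl, because the build behind the array annotation is not named.

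Values were transformed as log2(intensity + 16). Fold changes are on this scale, which understates the change of genes with low signal. The 60% of probe sets with the highest mean over all 6 arrays were tested, 13576 in all, the dimmest with a mean level equal to an intensity of 17.3. No further normalization between arrays was applied. Differences between the genotypes were tested with limma 3.58.1 (lmFit and eBayes with an intensity trend, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over the tested probe sets and a threshold of 0.05. The median standard error of a log2 fold change was 0.13. Per gene, the tested probe set with the highest mean was used.

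Gene sets were 32 lists of 19 pathway and 13 cell type groups, of which 31 had at least 3 measured members. Each was tested with limma's camera at a preset inter-gene correlation of 0.01, and also with an estimated correlation and with fry, adjusted over the lists. "Adjusted over the list alone" means Benjamini-Hochberg over the members of 1 list. Some genes are in more than 1 list, such as Gh, Ghrhr and Lcn2.

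The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule takes Arntl, then the 12 genes up and 12 down with the largest absolute log2 fold change among those past the threshold whose genotypes do not overlap. It adds every measured member of the E-box-driven, REV-ERB-repressed and hormone subunit lists, and up to 4 members past the threshold from each other list, or 2 with the smallest p where none passed. Not every gene the rule takes is printed. A few further list members are named for contrast. Genes under Other observations were chosen after their values were seen.

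Alternatives were pseudocounts of 1 and 64, quantile normalization, equal array medians, no filter on low values, the top 40% of probe sets, eBayes without the trend or with robust estimation, estimated array weights, and each array left out in turn. For the count of changed probe sets, other thresholds, an ordinary test without moderation, the removal of probe sets ending in _x_at or _s_at, and the removal of genes within 20 Mb of Arntl were tried too. For the lists, the mean of all probe sets of a gene was also used.

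The procedure was tested on simulated data for this comparison with 13576 probe sets in 10 simulations. It recovered 51.8% of simulated changes of 0.5 on the log2 scale, 99.6% of changes of 1 and 100% of changes of 2, and 5.18% of calls were false. A list of 15 probe sets shifted by 0.4 was called in 100% of simulations and an unshifted one in 0%. The simulated probe sets varied independently of each other, with a spread set by their intensity alone. These rates therefore do not carry over to lists of correlated genes or to probe sets whose spread departs from the trend.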

Results

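Whole pituitary glands of male mice were profiled on 6 Affymetrix 3' expression arrays, 3 of wild-type animals (replicates 1 to 3) and 3 labelled Bmal1-/- (replicates 4 to 6). BMAL1, encoded by Arntl, is the transcription factor that pairs with CLOCK or NPAS2 to drive the circadian clock, and mice without it lose daily rhythms in constant darkness. Each array carried RNA pooled from 3 glands, so each replicate is a separate group of animals. All glands were taken at zeitgeber time 12, the moment of lights off. The question the design poses is which pituitary transcripts depend on BMAL1 at that time of day. Values are linear intensities, and n = 3 arrays per genotype throughout. The number of arrays limits the precision.

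The arrays resembled each other closely. Pearson's r between arrays, across the tested probe sets, was 0.980 to 0.986 within a genotype and 0.970 to 0.976 between genotypes. Wild-type replicate 2 lay nearest the arrays labelled Bmal1-/-, at 0.975 to 0.976, against 0.970 to 0.972 for wild-type replicates 1 and 3. Its r with those 2 wild-type arrays was higher, at 0.980 and 0.981. At most 0.302% of tested probe sets had identical values on any pair of arrays, so no array was a copy of another. Over all probe sets but the controls, the median intensity was 33.9 ± 0.404 (SD) in wild type and 31.9 ± 0.265 on the arrays labelled Bmal1-/-, with no overlap between genotypes. Control probe sets for the B1 and B2 repeat elements also read lower on those arrays, at 4115 ± 363 against 5148 ± 77.1 for B1 and 4676 ± 266 against 5608 ± 310 for B2. These 3 differences each reached the exact two-sided permutation p of 0.1, the smallest that 3 arrays against 3 allow. Over the tested probe sets alone, the median log2 level was 6.751 ± 0.002 in wild type and 6.752 ± 0.003 on the arrays labelled Bmal1-/-, with overlap. The 3'/5' signal ratio of the Actb control, a measure of RNA integrity, was 0.80 ± 0.09 on the log2 scale in wild type and 0.74 ± 0.13 on the arrays labelled Bmal1-/-, and that of Gapdh was -0.59 ± 0.08 and -0.70 ± 0.08. Both ratios overlapped between the genotypes.

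The targeted gene itself, Arntl, rose on the arrays labelled Bmal1-/-. Its single tested probe set read 43.3 ± 7.29 in wild type and 114 ± 12.8 on the arrays labelled Bmal1-/-, a log2 fold change of 1.13 (SE 0.14, limma adjusted p = 0.000653). The 3 wild-type arrays read 39.6, 51.7 and 38.6, and the 3 others 112.1, 102 and 127.5. The position of this probe set relative to the deleted part of the gene is not given in the sources used here. A probe set outside the deleted part checks nothing about the labels, so every direction below is relative to arrays labelled Bmal1-/-.

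Clock genes were among the largest changes in both directions. Nr1d2, which encodes the transcriptional repressor REV-ERB beta, fell from 1273 ± 174 to 78.4 ± 13.9, a log2 fold change of -3.77 (SE 0.13, adjusted p = 1.21e-08). Dbp, a PAR-domain transcription factor driven directly by BMAL1, fell from 440 ± 59.1 to 68.6 ± 11.1 (log2 fold change -2.43, SE 0.13). Npas2, the paralogue of CLOCK, rose from 3.33 ± 3.20 to 119 ± 13.5 (log2 fold change 2.81, SE 0.16). Cry1, a repressor in the core feedback loop, rose from 102 ± 11.3 to 422 ± 54.6 (log2 fold change 1.89, SE 0.12).

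Of 15 listed clock genes driven through E-boxes, the DNA element that BMAL1 binds, 13 were measured, 8 fell, 1 rose and 4 did not pass the test. Adjusted over the list alone, 9 fell and 2 rose. Besides Nr1d2 and Dbp, the genes that fell were Nr1d1 (REV-ERB alpha, -1.95, SE 0.17), Per3 (-1.54, SE 0.16), Wee1 (a kinase that holds back mitosis, -0.92, SE 0.14), Usp2 (-0.90, SE 0.12), Tef (-0.85, SE 0.10) and Per1 (-0.53, SE 0.13). Hlf, a PAR-domain factor related to Dbp and Tef, rose by contrast from 180 ± 30.1 to 281 ± 39.9 (log2 fold change 0.61, SE 0.13). Per2, Bhlhe40, Nampt and Cry2 did not pass, with log2 fold changes of -0.54, -0.27, -0.01 and 0.35. The list as a whole was shifted downward by limma's camera test (adjusted p = 2.04e-09 at a preset correlation of 0.01). With an estimated correlation that call was lost (adjusted p = 0.252). The Per1 call was lost when any array but wild-type replicate 2 was left out (highest adjusted p = 0.138, without wild-type replicate 3), and the Hlf call without wild-type replicate 1 or Bmal1-/- replicate 5 or 6 (highest 0.0899, without replicate 5). Both calls also ended with no filter on low values (Per1 0.0891, Hlf 0.0661) and without the intensity trend in the variance model (0.0657 and 0.0729). Wee1 lies within 20 Mb of Arntl, a region with more called genes than elsewhere.

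All 4 listed genes that REV-ERB represses rose. After Npas2 and Cry1 came Nfil3, a repressor that competes with DBP for its sites, which went from 57.5 ± 5.50 to 158 ± 28.4 (log2 fold change 1.23, SE 0.14). Clock rose from 108 ± 6.23 to 185 ± 6.30 (log2 fold change 0.70, SE 0.10). The list was shifted upward (camera adjusted p = 7.78e-10), with adjusted p = 0.0765 with an estimated correlation. Of 10 measured other clock components only Csnk1d, a kinase that phosphorylates PER proteins, rose (log2 fold change 0.44, SE 0.08). It missed the threshold without the intensity trend in the variance model (adjusted p = 0.0511). Rora, Rorb and Gsk3b were within 0.03 of 0 on the log2 scale.

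**Figure D1:**
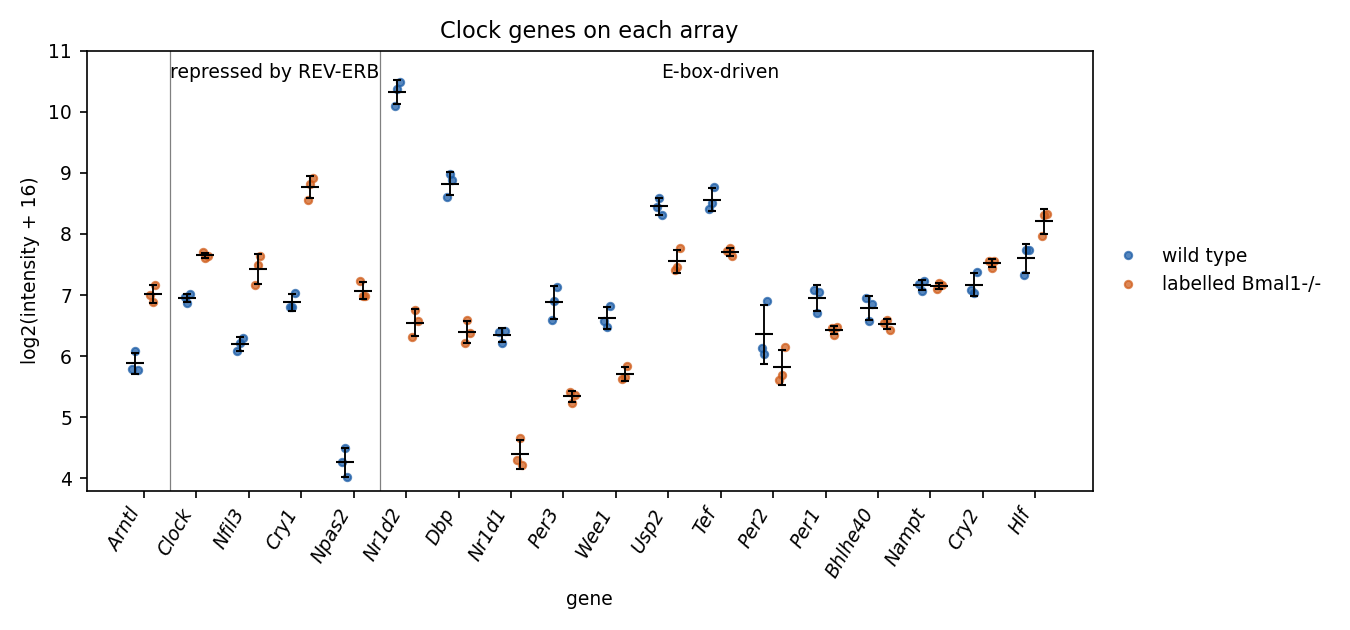
Level of Arntl, 4 genes repressed by REV-ERB and 13 E-box-driven clock genes on each of 6 arrays (points, log2 of intensity plus 16), with the mean and SD of each genotype as black bars. Arntl and all 4 REV-ERB-repressed genes sit higher on the arrays labelled Bmal1-/-, while Nr1d2 drops from a mean of 1273 to 78.4 intensity units.

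Across the array, 752 of 13576 tested probe sets changed at an adjusted p under 0.05 in limma, 374 higher and 378 lower on the arrays labelled Bmal1-/-. Counting 1 probe set per gene, 455 of 8033 genes changed, 241 upward and 214 downward. Most changes were small. The median absolute log2 fold change among called probe sets was 0.58, and 72 changed over 2-fold, 35 of them higher and 37 lower. The genotypes did not overlap at 751 of the 752, and at 25.9% of all tested probe sets where chance gives 10%. Leaving out 1 array changed the count: it was 425, 950 and 314 without wild-type replicates 1, 2 and 3. Without Bmal1-/- replicates 4, 5 and 6 it was 425, 329 and 410. Each of these fits also has fewer arrays. A call lost in such a fit, here or elsewhere, does not by itself show that the change rests on the array left out. With all 6 arrays the count fell to 330 with no filter on low values and to 407 without the intensity trend in the variance model.

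Outside the clock, the genes with large rises included Gdpd3, Nmu and Pla2g7. Gdpd3, a lysophospholipase D, rose from 47.3 ± 40.4 to 334 ± 116 (log2 fold change 2.74, SE 0.50). Without wild-type replicate 1, which read 0.7, it was 1.95. Its call was lost with robust eBayes (adjusted p = 0.160), a pseudocount of 1 (adjusted p = 0.0555) or no filter on low values (adjusted p = 0.0501), and it lies within 20 Mb of Arntl. Nmu, which encodes the neuropeptide neuromedin U, rose from 7.53 ± 2.49 to 67.5 ± 16.7 (log2 fold change 1.81, SE 0.17). Pla2g7, which inactivates platelet-activating factor, rose from 134 ± 9.56 to 425 ± 13.1 (log2 fold change 1.56, SE 0.09). Other genes among the 12 with the largest rise were the matricellular gene Ccn3 (1.61), the integrin ligand Npnt (1.56), Fam162a (1.35), Zfp385a (1.35), Cmtm7 (1.34) and Cpxm2 (1.27), each with SE between 0.12 and 0.22. Cpxm2 also lies within 20 Mb of Arntl.

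Among the 12 genes that fell furthest, 4 were the clock genes Nr1d2, Dbp, Nr1d1 and Per3. Ces1d, a carboxylesterase, fell from 101 ± 38.7 to 7.90 ± 2.62 (log2 fold change -2.24, SE 0.21). Grem1, a secreted antagonist of bone morphogenetic proteins, fell from 61.0 ± 2.15 to 10.1 ± 0.666 (log2 fold change -1.56, SE 0.14), and Ceacam10 fell from 204 ± 12.4 to 58.3 ± 11.1 (-1.58, SE 0.13). Lcn2, an iron-siderophore binding lipocalin, fell from 375 ± 103 to 117 ± 18.8 (-1.53, SE 0.16). Rbp4, the plasma carrier of retinol, fell from 190 ± 15.1 to 70.2 ± 5.21 (-1.26, SE 0.11). The serine protease genes Klk1b27, a kallikrein (-1.47, SE 0.24), and Prss28 (-1.31, SE 0.21), and the TRIM-family gene Trim34a (-1.29, SE 0.26) completed the group. Trim34a missed the threshold without wild-type replicate 1 (adjusted p = 0.0581) and with no filter on low values (adjusted p = 0.0616), and it too lies within 20 Mb of Arntl.

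**Figure D2:**
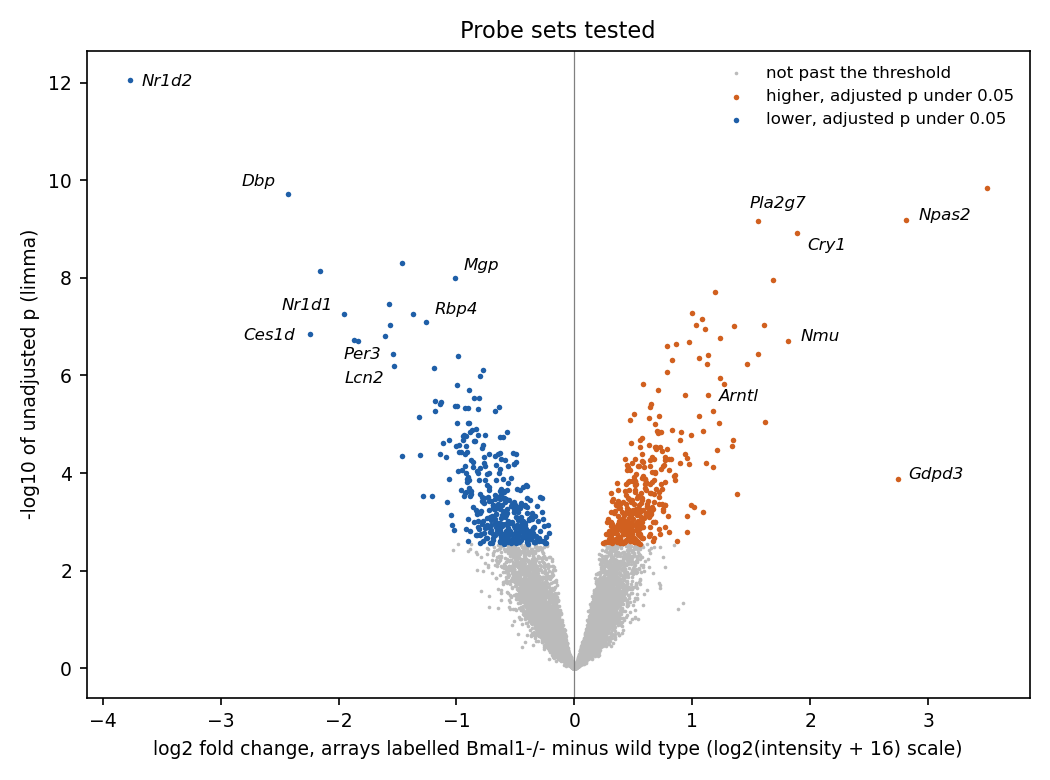
Log2 fold change (arrays labelled Bmal1-/- minus wild type, 3 arrays each) against -log10 of the unadjusted limma p for 13576 tested probe sets, coloured by direction where the adjusted p was under 0.05. The 374 higher and 378 lower probe sets are near balance, with Nr1d2 lowest at -3.77 and Npas2 at 2.81.

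Hormone transcripts, among the brightest on the arrays, differed little. Of the 7 hormone subunits, 2 fell: Cga, the alpha subunit shared by the glycoprotein hormones, from 10490 ± 847 to 8426 ± 332 (log2 fold change -0.31, SE 0.07, adjusted p = 0.0190), and Gh, growth hormone, from 19355 ± 1119 to 16017 ± 662 (-0.27, SE 0.06, adjusted p = 0.0217). The 3 other Gh probe sets were also below 0, and 2 of them passed. The Gh calls followed below are those of its brightest probe set alone. Pomc (-0.24), Fshb (-0.28), Prl (-0.11), Tshb (-0.04) and Lhb (0.18) did not pass over all probe sets, though without wild-type replicate 2 Pomc (-0.30, adjusted p = 0.0232) and Fshb (-0.38, adjusted p = 0.0167) did. Adjusted over the list alone, 4 fell. The list was shifted downward (camera adjusted p = 0.0233), with adjusted p = 0.539 with an estimated correlation. The brightest probe sets moved the same way: of the 100 brightest outside the hormone and somatotroph lists, 87 were below 0, with a median log2 fold change of -0.11. After quantile normalization the list's camera adjusted p was 0.960. That step gives each rank 1 value, and Gh is the brightest tested probe set on all 6 arrays while Prl, Pomc and Cga rank between 4 and 8, so it says nothing about whether these genes changed. The Gh call was lost with no filter on low values (adjusted p = 0.125) and without the variance trend (0.169), the Cga call likewise (0.0918 and 0.139), and the list's call with no filter (0.0557). Leaving out 1 array ended the Gh call (without wild-type replicate 1 or 3 or Bmal1-/- replicate 5 or 6, highest adjusted p = 0.0996) and the Cga call (without wild-type replicate 3 or Bmal1-/- replicate 4 or 6, highest 0.0834), and the list's call without wild-type replicate 3 (0.153) or Bmal1-/- replicate 6 (0.0923).

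Of 10 measured receptors for releasing factors and feedback hormones, 2 fell and none rose. Ghrhr, the receptor for growth hormone-releasing hormone, fell from 561 ± 85.4 to 347 ± 30.4 (log2 fold change -0.66, SE 0.11), and Sstr2, a somatostatin receptor, from 26.8 ± 3.83 to 11.8 ± 2.40 (-0.62, SE 0.16). Nr3c1, the glucocorticoid receptor, had a log2 fold change of -0.50 (adjusted p = 0.0639). Adjusted over the list alone, 4 fell. The list was shifted downward (camera adjusted p = 0.0458, and adjusted p = 0.301 with an estimated correlation), a call lost after quantile normalization (0.0802), with no filter on low values (0.118), and without wild-type replicate 1 (0.0644), wild-type replicate 3 (0.438) or Bmal1-/- replicate 5 (0.0698). The Sstr2 call was lost after quantile normalization (adjusted p = 0.0798), with no filter (0.10), and without any 1 of the Bmal1-/- replicates 4, 5 and 6 (highest 0.139).

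Of 12 measured pituitary transcription factors, 2 rose: Six6, a homeobox gene of the ventral brain and pituitary, from 493 ± 26.0 to 675 ± 14.2 (log2 fold change 0.44, SE 0.07), and Lhx3, required for most anterior lobe lineages, from 465 ± 25.2 to 570 ± 7.84 (0.29, SE 0.08). The Lhx3 call was lost when any 1 of the 6 arrays was left out (highest adjusted p = 0.147). In the list of secretory granule and exocytosis genes, 23 were measured, 3 rose and 2 fell. Stx1a, a membrane fusion protein of exocytosis, rose from 52.4 ± 9.66 to 119 ± 26.7 (0.97, SE 0.16). The prohormone convertase gene Pcsk1 fell (-0.50, SE 0.11), as did Pam, which amidates peptide hormones (-0.65, SE 0.13), while Pcsk1n, an inhibitor of the PCSK1 enzyme, rose (0.32, SE 0.08). Leaving out 1 array ended the calls of Pcsk1 (highest adjusted p = 0.0866, without wild-type replicate 3, and also without Bmal1-/- replicate 5), Pam (0.0536, without Bmal1-/- replicate 4) and Pcsk1n (0.156, without Bmal1-/- replicate 4, and with any other but wild-type replicate 2). Adjusted over the list alone, 5 transcription factors rose, and 4 secretory genes rose and 4 fell. Neither list was shifted, with camera adjusted p of 0.0917 and 0.614.

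All 18 measured genes of the glucocorticoid-induced list had log2 fold changes below 0, and 5 of them fell. Fkbp5, a chaperone that limits glucocorticoid receptor activity, fell from 471 ± 27.1 to 280 ± 63.0 (log2 fold change -0.74, SE 0.13). Lcn2 (-1.53), the sulfotransferase gene Sult1a1 (-0.98, SE 0.15), the transcription factor Cebpb (-0.82, SE 0.20) and Ddit4, an inhibitor of mTOR signalling (-1.02, SE 0.25), fell as well. Adjusted over the list alone, 9 fell. The metallothioneins Mt1 and Mt2 and the leucine zipper gene Tsc22d3 had log2 fold changes of -0.35, -0.50 and -0.44 and did not pass. The list's median was -0.42 and its camera adjusted p = 5.99e-08, with adjusted p = 0.252 with an estimated correlation. Sult1a1 lies within 20 Mb of Arntl, Lcn2 is also a folliculostellate marker, and Cebpb lost its call without wild-type replicate 1 or 3 or Bmal1-/- replicate 4 or 6 (highest adjusted p = 0.138). The Ddit4 call (limma adjusted p = 0.0355) was not followed through the alternatives.

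None of 15 immediate early genes passed, with the smallest p-values at Ccn1 (-0.56, adjusted p = 0.0596) and Btg2 (0.36, adjusted p = 0.164). All but Btg2, 14 of the 15, were below 0, with a list median of -0.22. Of 19 heat shock chaperones 5 rose. They included Hspa8, the constitutive HSC70 chaperone, from 2323 ± 316 to 3398 ± 293 (log2 fold change 0.55, SE 0.09, with 1 of its 3 other probe sets rising and 2 not past, at -0.07 and -0.24), and Fkbp4, a co-chaperone of steroid receptors, from 161 ± 26.4 to 252 ± 7.72 (0.61, SE 0.11), with Hsph1 (0.41) and Ahsa1 (0.31). The inducible genes Hspa1a and Hspa1b had log2 fold changes of -0.07 and -0.45 and did not pass. In the endoplasmic reticulum stress list of 23 genes, Sdf2l1 rose (0.45, SE 0.09) and Asns, asparagine synthetase, fell (-0.39, SE 0.09). In the antioxidant list of 21, Txnrd1 rose (0.45) while Gstm1 (-0.36), Mgst1 (-0.49) and Nfe2l2, which encodes the NRF2 factor (-0.36), fell. These 4 lists were not shifted, at camera adjusted p of 0.0874, 0.0917, 0.506 and 0.613, and the antioxidant list had a median of 0.03 and a mean of -0.06. The immediate early list passed without wild-type replicate 1 (0.0251) or Bmal1-/- replicate 5 (0.00387), downward. The heat shock list passed upward without wild-type replicate 1 (0.0209), with no filter on low values (0.0453) and with all probe sets of a gene averaged (0.0204). The calls of Hsph1, Ahsa1, Sdf2l1, Asns, Txnrd1, Gstm1, Mgst1 and Nfe2l2 each ended with at least 4 of the 6 omissions of 1 array, and every array ended at least 1 of them (highest adjusted p = 0.140, Ahsa1 without Bmal1-/- replicate 6). The Hspa8 call was lost without the intensity trend in the variance model (adjusted p = 0.0570).

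Energy metabolism genes moved singly. Of 18 glycolysis genes 3 rose: Pfkp, a phosphofructokinase, from 171 ± 5.23 to 307 ± 0.866 (log2 fold change 0.79, SE 0.09), Ldha, lactate dehydrogenase A, from 273 ± 27.2 to 395 ± 20.5 (0.51, SE 0.09), and Hk1, hexokinase (0.37, SE 0.08). Of 30 oxidative phosphorylation genes, Atp5b (0.49) and Sdhc (0.41, its other probe set -0.32 and not past) rose and Uqcrfs1 (-0.44) fell. None of 19 sterol and fatty acid synthesis genes passed, with Elovl6 (-0.28, adjusted p = 0.166) and Scd1 (-0.19, adjusted p = 0.355) nearest. Of 19 interferon-induced genes Rsad2 rose (0.57) and Ifit3 fell (-0.66). None of the 4 lists was shifted, at camera adjusted p of 0.613, 0.649, 0.847 and 0.490. Leaving out 1 array ended the calls of Hk1, Sdhc, Rsad2 and Ifit3 with 4 of the 6 omissions each, every array among them, of Uqcrfs1 with 2, without wild-type replicate 3 or Bmal1-/- replicate 5, and of Atp5b without Bmal1-/- replicate 6. The highest adjusted p was 0.133, for Rsad2 without Bmal1-/- replicate 5.

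Among cell cycle genes, none of 13 measured S and M phase members passed, with Mcm7 at 0.32 (adjusted p = 0.108) and Nusap1 at -0.21 (adjusted p = 0.499). Of 17 CDK inhibitors and regulators of G1, 2 rose. Mycn, a MYC-family transcription factor, went from 72.0 ± 4.24 to 153 ± 14.1 (log2 fold change 0.94, SE 0.11), and Cdkn2b, which encodes the CDK4 and CDK6 inhibitor p15, from 25.6 ± 3.07 to 76.0 ± 23.0 (1.11, SE 0.19). Of 15 paraspeckle and nuclear RNA-binding genes Hnrnpa1 fell (-0.48, SE 0.11), a call lost without wild-type replicate 1 or 3 or Bmal1-/- replicate 5 or 6 (highest adjusted p = 0.109). The lists were not shifted, at camera adjusted p of 0.649, 0.613 and 0.613. In the CDK inhibitor list the median was -0.02 while the mean was 0.11 and the test pointed upward.

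Markers of growth hormone cells fell together. All 4 measured somatotroph markers passed: Wnt10a, a WNT ligand, from 183 ± 42.4 to 88.7 ± 8.90 (log2 fold change -0.91, SE 0.14), Ghrhr (-0.66), Dlk1, a Notch-related surface protein, from 6407 ± 360 to 5244 ± 440 (-0.29, SE 0.07), and Gh (-0.27). The list was shifted downward (camera adjusted p = 5.27e-05, and adjusted p = 0.252 with an estimated correlation), and 2 of its genes are also in the lists above. Dlk1 and Gh are among the brightest probe sets, and the Dlk1 call was lost after quantile normalization (-0.12, adjusted p = 0.390) and when any array but Bmal1-/- replicate 4 was left out (highest adjusted p = 0.149, without replicate 5). Wnt10a and Ghrhr kept their calls in every alternative.

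Markers of the other hormone cells did not shift as lists. Dio2, the deiodinase that activates thyroid hormone, was the only thyrotroph marker of 4 to change, rising from 195 ± 25.5 to 438 ± 16.5 (log2 fold change 1.11, SE 0.10). Of 4 corticotroph and melanotroph markers Gal, which encodes galanin, fell from 66.0 ± 12.2 to 26.8 ± 1.83 (-0.93, SE 0.15). Of 7 lactotroph markers only Gstm7 rose (0.53, SE 0.14), a call lost when any 1 of the 6 arrays was left out (highest adjusted p = 0.17). None of 4 gonadotroph markers passed, with Fshb and Lhb nearest. Camera adjusted p was 0.0874, 0.0716, 0.649 and 0.613 for these 4 lists, and the lactotroph median (-0.02) and mean (0.17) had opposite signs. Without Bmal1-/- replicate 6, or after quantile normalization, the thyrotroph list passed (0.0465 and 0.0484). The corticotroph list passed without wild-type replicate 2 (0.0329) and when all probe sets of a gene were averaged (0.0384).

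Of 13 measured connective tissue and pericyte markers 10 were below 0, 3 fell and 1 rose. Mgp, an inhibitor of calcification, fell from 891 ± 28.3 to 433 ± 22.3 (log2 fold change -1.01, SE 0.07), Dcn, a small proteoglycan, from 479 ± 21.3 to 269 ± 23.0 (-0.80, SE 0.09), and Rgs5, a pericyte regulator of G-protein signalling, from 684 ± 58.8 to 392 ± 14.4 (-0.77, SE 0.08). Col1a2, a chain of type I collagen, rose from 651 ± 23.6 to 804 ± 47.7 (0.30, SE 0.07), while its other probe set did not pass (-0.07, SE 0.09). The Col1a2 call was lost after quantile normalization (adjusted p = 0.0537) and without wild-type replicate 1 or 3 or Bmal1-/- replicate 5 or 6 (highest 0.140). The list was shifted downward (camera adjusted p = 0.00125, and adjusted p = 0.301 with an estimated correlation). Of 17 macrophage and leukocyte markers 16 were below 0, and C1qa, a complement subunit, fell from 127 ± 7.26 to 86.2 ± 5.59 (-0.48, SE 0.11), a call lost when any 1 array was left out (highest adjusted p = 0.0898). That list was shifted downward (camera adjusted p = 0.0112, and adjusted p = 0.412 with an estimated correlation), but not without wild-type replicate 1 (0.0644) or Bmal1-/- replicate 6 (0.0923).

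Of 12 folliculostellate and stem cell markers, Aldh1a2, a retinoic acid synthesising enzyme, rose from 325 ± 52.3 to 488 ± 14.6 (log2 fold change 0.58, SE 0.10) and Rbpms rose (0.60, SE 0.11), while Cyp2f2 fell from 1093 ± 79.2 to 619 ± 83.7 (-0.81, SE 0.10) and Lcn2 fell. Of 5 myelin markers Ugt8a, which makes galactosylceramide, fell (-0.90, SE 0.12) and Mbp, myelin basic protein, rose (0.52, SE 0.11). The Mbp call was lost without wild-type replicate 3 or Bmal1-/- replicate 4 or 5 (highest adjusted p = 0.0838). Of 11 endothelial markers Plvap rose (0.40, SE 0.09), a call lost without wild-type replicate 1 or 3 or Bmal1-/- replicate 4 or 5 (highest adjusted p = 0.103). No posterior lobe or erythroid marker passed, with Oxt (-0.57, adjusted p = 0.0565) and Nefm (-0.51, adjusted p = 0.0684) nearest in the former and Alas2 (-0.26) and Car2 (0.16) in the latter. Camera adjusted p was 0.613, 0.847, 0.613, 0.0729 and 0.658 for these 5 lists, in the order given. All 4 posterior lobe markers were below 0, and 2 fell when adjusted over the list alone. Oxt passed without wild-type replicate 2 (0.0133) and with array weights (0.0397), Nefm without wild-type replicate 2 (0.0448), and the list without wild-type replicate 2 (0.0412) or Bmal1-/- replicate 6 (0.0465). The folliculostellate and myelin lists had medians above 0 (0.04 and 0.19) and means below 0 (-0.13 and -0.05). From the muscle and bone list only Pvalb was measured (0.24, adjusted p = 0.443), so that list was not tested.

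In all, 8 of the 31 testable lists were shifted at the preset correlation, 1 upward and 7 downward, and none with an estimated correlation (lowest adjusted p = 0.0765). The estimated correlation was below the preset 0.01 in the REV-ERB-repressed (-0.20) and receptor (-0.005) lists. For these lists a higher correlation does not explain the lost call, yet their unadjusted camera p rose from 2.51e-11 to 0.00247 and from 0.0118 to 0.0582. The setting thus raises p-values even where the correlation is not higher. Calls lost with it therefore do not show that correlation between genes alone accounts for the loss. Limma's fry test, which asks whether a list's genes move on balance 1 way, called 7 lists, and 6 of these were among the 8. The hormone subunit (adjusted p = 0.173) and macrophage (0.0887) lists were not called by it, and the corticotroph and melanotroph list was (0.0464).

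**Figure D3:**
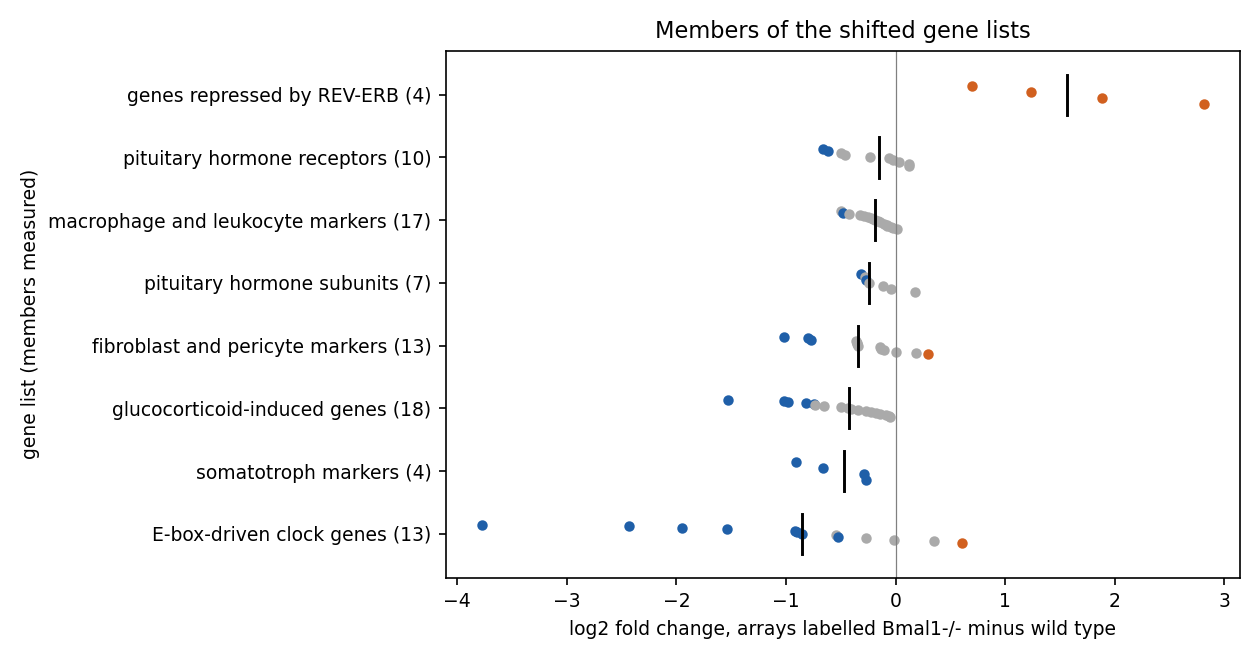
Log2 fold changes (arrays labelled Bmal1-/- minus wild type) of the measured members of the 8 lists shifted by camera, 1 point per gene, orange where a gene rose, blue where it fell, grey where it did not pass, with the list median as a black bar. The medians run from 1.56 for genes repressed by REV-ERB to -0.85 for E-box-driven genes. All 18 glucocorticoid-induced genes lie below 0.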

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

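No paired analysis was possible because the groups share no replicate numbers. Arntl stayed higher on the arrays labelled Bmal1-/- in every alternative, with a log2 fold change from 0.73 (pseudocount 64) to 1.38 (pseudocount 1), and between 1.06 and 1.23 as each array was left out. Of 103 named genes none changed direction while past the threshold. Of the 83 past it, 48 stayed past it in every alternative that tested them and 35 did not in at least 1. The 4 REV-ERB-repressed genes passed wherever tested, and 6 to 8 E-box-driven genes fell. Calls lost both with no filter on low values and without the intensity trend were those of Hlf, Per1, Cga, Gh, Lhx3, Pcsk1, Pcsk1n, Hnrnpa1, Cebpb, Hsph1, Ahsa1, Asns, Gstm1, Nfe2l2, Mgst1, Atp5b, Rsad2, Dlk1, Plvap and Col1a2. The calls of Gdpd3, Trim34a, Sstr2, Ifit3, Gstm7 and C1qa were lost with no filter only of these settings, and those of Csnk1d, Pam, Hspa8, Sdf2l1, Txnrd1, Uqcrfs1, Sdhc and Hk1 without the trend only.

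The count of changed probe sets depended on several settings. Against 752 (374 higher, 378 lower), it was 330 (176 and 154) with no filter on low values, of which 305 were shared, and 407 (189 and 218) without the intensity trend. At an adjusted p under 0.10 it was 1403 (662 and 741), and 432 (157 higher) at an unadjusted p under 0.01 with a change over 1.5-fold. An ordinary test without moderation, which estimates each spread from 6 values alone, called 32 (20 and 12). Leaving out 1 array gave 314 to 950 changed, 160 to 427 higher and 142 to 523 lower, with fewer arrays in the fit each time. Quantile normalization gave 679 calls, 648 of them shared. The share of calls that were higher was 49.7% as deposited, 52.3% after quantile normalization and 49.3% with equal medians.

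The count of other clock components that changed was 0 without the trend against 1, and from 1 to 2 as arrays were left out. The 8 shifted lists became 0 with an estimated inter-gene correlation and 6 to 10 as arrays were left out, and 5 of the 8 stayed called in every alternative at the preset correlation. The cause of these shifts was not tested. With no detection calls, the lower end of the signal range limits the fold changes of dim genes such as Npas2 and Nr1d1.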

Other observations

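Some gene families outside the fixed lists held several called genes. They were chosen after their values were seen. Of their members named below, only the calls of Grem1 and Klk1b27 were followed through the alternatives. Id1, Id3 and Id4, which encode inhibitors of basic helix-loop-helix factors and are known targets of bone morphogenetic protein signalling, rose by 0.77, 0.64 and 1.23 on the log2 scale, 3 of 4 measured members. Among 7 measured bone morphogenetic protein ligands and antagonists, Bmp6 rose from 70.4 ± 8.73 to 173 ± 8.20 (log2 fold change 1.13, SE 0.11), and the antagonists Grem1 (-1.56) and Chrd (-0.98, SE 0.16) fell, while 4 did not pass. Of these 7 genes 6 were below 0, with a median of -0.28. Of 7 annexins Anxa5 rose (0.47), Anxa4 (-0.36) and Anxa7 fell and 4 did not pass. The Id median was 0.70 as deposited and 0.73 after quantile normalization.

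The immunoglobulin genes Igha (109 ± 4.88 to 38.7 ± 5.58, log2 fold change -1.19) and Igkv8-30 (-0.93) fell, 2 of 3 measured, as did the kallikreins Klk1 (-0.92), Klk1b16 (-0.89) and Klk1b27 (-1.47) out of 5 measured, and both family medians stayed below 0 after quantile normalization (-0.86 and -0.83). Most of these had low signal: mean intensity went from 32.0 to 9.53 for Igkv8-30, 38.4 to 12.7 for Klk1, 54.4 to 23.5 for Klk1b16 and 57.7 to 11.3 for Klk1b27. Hsd11b1, which regenerates active glucocorticoid, fell from 126 ± 17.0 to 54.1 ± 5.51 (-1.02, SE 0.13). Tgm2, a transglutaminase, fell at 4 of 5 probe sets, with log2 fold changes of -0.89 to -1.18.

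Some genes gave different answers from different probe sets. Thra rose at 1 probe set (157 ± 11.4 to 323 ± 13.6) but not at the other (32.0 ± 4.58 to 38.0 ± 6.77), a difference of 0.80 (SE 0.18), and the gene overlaps Nr1d1. Of 80 genes with more than 1 called probe set, Rdx and Hadh were called in both directions. Actb was unchanged at its brightest probe set (0.00, SE 0.06) and fell at another (-0.87, SE 0.12). A probe set annotated to several genes, and so not named, rose from 4.33 ± 4.42 to 212 ± 33.3. Hspa8 rose at 2 of 4 probe sets, and Col1a2 and Sdhc at 1 of 2. Csnk1d rose at 1 of 5. Among pericyte genes, Pdgfrb and Rgs5 differed by 0.67 (SE 0.16). This SE and that of the Thra difference treat the 2 probe sets as independent, though both were read on the same arrays.

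All tests below were chosen after the result was seen, except those of other splits of the arrays and of the direction of neighbouring genes' other probe sets, counted by probe set. Of the 10 ways to split the 6 arrays into 3 and 3, the real one gave 752 changed probe sets and the highest other 1. For shifted lists the real split gave 8 and the highest other 6. In each case only 1 split, the real one, gave as many, and 10 splits are too few for a share under 0.05.

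The Arntl probe set read higher on the arrays labelled Bmal1-/-. An exchange of the genotype labels would raise E-box-driven genes on those arrays, but their median log2 fold change was -0.85. A single wrong label would place 1 array with the other genotype, but the closest arrays of the groups lay 0.85 apart in the mean log2 level of all 13 measured E-box-driven genes, against a largest SD of 0.13 within a group. A candidate explanation is that the probe set reads a part of the transcript that remains and is freed from repression by REV-ERB, since Arntl is itself a REV-ERB target: the other REV-ERB-repressed genes had a median of 1.56. The sequence of the probes and of the deleted part was not used here, so this stays a hypothesis.

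Called genes were more frequent near Arntl. Within 20 Mb of it 21 of 186 genes changed (11.3%), against 5.52% elsewhere, an odds ratio of 2.18 (Fisher's exact p = 0.00206, Benjamini-Hochberg adjusted 0.00412 over 4 window sizes), and the share exceeded that around 98.7% of 7336 other genes. The odds ratio was 4.04 within 5 Mb and 1.78 within 40 Mb. This is consistent with DNA of another strain carried along with the targeted allele, though a local effect of the deletion itself was not tested. Base differences under single probe sets alone would leave other probe sets of the same gene unmoved, yet 93.75% of them (15 of 16) shared the direction. Probe sets of 1 gene are not independent, and counted by gene it was 9 of 10 (exact binomial p = 0.0215). Only 4 of the 16 passed the threshold themselves. Eif3c supplied 3 of the 16 and Tmem41b 4. Probe sequences were not used, so it is not known whether 1 base difference could move several probe sets of a gene. For the 11 genes with 1 tested probe set, Gdpd3 and Wee1 among them, base differences cannot be told apart from a change in level.

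The 4 somatotroph markers fell by different amounts. For Dlk1, a lower signal of the brightest probe sets may account for it: 87% of the 100 brightest other probe sets were below 0, and its log2 fold change went from -0.29 (SE 0.07) to -0.12 (SE 0.07) after quantile normalization, which ended the call. For Gh this cannot be told apart from a fall of its own, since it is the brightest probe set on all 6 arrays and quantile normalization then fixes its value. Ghrhr ranks between 1007 and 2286 and Wnt10a between 3082 and 7502. The median over the 1000 brightest other probe sets was only -0.003, which argues against a lower bright signal as the cause for Ghrhr and Wnt10a. Quantile normalization could hardly move genes at those ranks, so Ghrhr at -0.69 (SE 0.11, limma adjusted p = 0.00607) after that step adds little. Fewer somatotrophs as the whole cause would raise the share of all other cells and lower the somatotroph markers alike. The mean log2 fold change of the 85 measured markers of other cell types was -0.11 (SE 0.03). That mean does not decide the question, since list means ran from -0.34 (posterior lobe) to 0.36 (thyrotroph). It includes the connective tissue (-0.30) and macrophage (-0.21) lists, which were themselves shifted downward. The fall of Ghrhr was larger than that of Gh (difference -0.39, SE 0.13) and Dlk1 (-0.37, SE 0.13), although compression at high signal would also give such differences. The SEs of these differences treat the genes as independent, though all were read on the same arrays, so they are approximate. Between the less bright Wnt10a and Ghrhr the difference was -0.25 (SE 0.18, taken the same way), so an equal fall of both is not excluded. Lower expression per cell, alone or with a smaller loss of cells, was not tested separately.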
